A study of Vuilleminia comedens with 3 samples.

How the data were processed

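Vuilleminia comedens is a crust-forming basidiomycete that decays wood of broadleaved trees. Per the labels' protocols, autoclaved beech blocks of 2 cm3 were colonised for about 8 weeks by strain VcWVJH1 on plates with 0.5% malt extract. Surface mycelium was then removed and pairs of blocks carrying the same strain were set against each other for 7 days at 20 °C. An elastic band held each pair at the start and was taken off after 3 days. RNA came from the parts of the blocks next to the contact face, poly(A) RNA was isolated with oligo(dT) beads, and stranded libraries were sequenced as paired reads of 125 bp. The labels describe the 3 libraries as independent biological replicates from separate blocks, made to inform a transcriptome assembly. They form 1 group, so no comparison between conditions was possible.

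The deposited count table held, for each assembled transcript, its length in bases and whole-number read counts in 3 columns, and these counts had not been normalised. Per the submitters' processing notes, cutadapt 1.2.1, Bowtie2 2.2.6 and SAMtools 0.1.19 were used, with no order or role stated. The transcript names follow the pattern of the Trinity assembler, but the assembler, its settings and the counting rule, including the use of strand, are not given in the sources used here. The count columns had no names, so they could be assigned to the group but not to single replicate numbers, and they are called libraries A, B and C here. The deposited annotation table paired transcripts with a best-matching entry, per the file headers from a search against a database built by the authors. The search tool and its thresholds are not given in the sources used here. Of its 29875 lines, repeated lines were removed, which left 22605 transcripts with 1 match each. A product name is that of the matched entry in another species and not a function measured in V. comedens.

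Counts were divided by the library total and multiplied by 1000000 for CPM, and divided by transcript length in kilobases for RPKM. Because 2 transcripts held most reads, summed reads are also given relative to 1000000 counts outside those 2, called residual CPM here. Before the data were examined, 33 word lists for gene families were fixed and matched to the annotation text without regard to case, and 4 areas of wood polymers were defined from them. For each list, the median RPKM was placed as a percentile among 10000 random lists of the same size, drawn with replacement from annotated transcripts matched on length decile. The limits for naming a list as high or low were the 97.5th and 2.5th percentiles. Transcripts are not replicates, so the percentile describes these libraries and no p-value is given. The word patterns took in some unrelated products. The list for viruses held antiviral helicases, that for plants ribulose-5-phosphate 3-epimerase, and that for bacteria a bacterial hemoglobin and a deaminase-reductase. The list for hydrogen peroxide-forming oxidases held 20 aryl-alcohol dehydrogenases. The list for glycolysis and the tricarboxylic acid cycle held 42 phosphoglycerate mutase-like proteins, 10 ATP-citrate synthases and 7 transaldolases. The list for heat shock proteins and chaperones held 5 copper chaperones, 4 vacuolar transporter chaperones and 2 permease chaperones. The oxalate and glyoxylate list held 8 2-isopropylmalate synthases, and the cell wall list 1 chitin synthase export chaperone.

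Agreement between libraries was described by Pearson and Spearman correlations across transcripts of log2(CPM + 1) and by the common biological coefficient of variation, estimated with edgeR 4.0.16 with no terms besides the intercept. Transcripts are not independent replicates, so these correlations carry no test. Shares of single libraries carry exact (Clopper-Pearson) 95% binomial intervals. Intervals and the floor of 3 counts cover counting error only, since PCR copies were not marked. Total counts ran from 64236917 to 111754018, and 3 counts corresponded to 0.0268 CPM in library A, 0.0440 CPM in library B and 0.0467 CPM in library C. Named transcripts followed a rule fixed beforehand. It took the 20 annotated transcripts with the highest RPKM among those of at least 300 bp and 100 reads, and the 2 highest of each list with at least 100 reads.

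The procedures were tested on simulated counts for the 81106 transcripts with the real totals and lengths. With a true coefficient of variation of 0.4, edgeR estimated 0.428. A list of 200 transcripts raised 4-fold lay at the 100th percentile, and 85 of 100 lists of 20 such transcripts lay above the upper limit. Of 100 lists of 50 transcripts drawn at random from all annotated ones, 1 fell outside the limits. These lists came from the same pool as the random lists, so few could be outside by construction. Alternatives covered the length scaling, minimum reads and length, summing by assembler gene, the background and matching of random lists, the summary of a list, TMM and DESeq2 1.42.0 scaling, omission of the 100 most-read transcripts and omission of each library. Restriction to Punctularia strigosozonata matches, omission of aryl-alcohol dehydrogenases and omission of transcripts read mainly in library A were chosen after the data had been seen. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and models in R 4.3.3. Transcript sequences were not analysed here.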

Results

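RNA was sequenced from 3 replicate pairs of beech blocks colonised by Vuilleminia comedens strain VcWVJH1, each pair holding the same strain on both sides. Libraries A, B and C held 111754018, 68151997 and 64236917 counts on assembled transcripts. Values below are means ± SD over these 3 libraries unless stated otherwise.

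The first question was how the reads were distributed over the transcripts. A transcript of 2132 bp, TRINITY_DN20091_c9_g1_i1, took 39.1% ± 3.45 (SD, n = 3) of the counts. A second of 3396 bp, TRINITY_DN24916_c10_g1_i1, took 29.7% ± 3.92 (SD, n = 3). Their best matches were the hypothetical proteins PUNSTDRAFT_78213 of Punctularia strigosozonata and STEHIDRAFT_48196 of Stereum hirsutum. Together they held 70.068% of the counts in library A (exact 95% interval 70.059 to 70.076), 67.003% in library B (66.992 to 67.015) and 69.259% in library C (69.247 to 69.270). The third most abundant transcript held 1.42% ± 0.464 (SD, n = 3). Outside the first 2 transcripts, 33450738, 22487890 and 19747416 counts remained in libraries A, B and C, and these set the precision for all other genes.

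The stated purpose of the libraries was an assembly, which comprised 81106 transcripts of 60736 assembler genes, up to 11506 bp long, with a median of 435 bp and an N50 of 1237 bp. A database match was present for 22605 transcripts, or 27.9%. Matched transcripts had a median length of 642 bp and unmatched ones of 403 bp. Of the matched transcripts, 41.3% carried the product name hypothetical protein. Fewer than 10 reads in total were counted for 18495 transcripts, and 133 had 0 reads in all 3 libraries.

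Matches fell mainly on Punctularia strigosozonata, a fungus of the order Corticiales like V. comedens, and on Trametes versicolor, a white-rot polypore. P. strigosozonata was the best match of 9543 transcripts with a median length of 1327 bp, and these took 54.6% ± 0.256 (SD, n = 3) of the counts outside the first 2 transcripts. T. versicolor was the best match of 11569 transcripts, but their median length was 342 bp and they took 13.4% ± 0.145 (SD, n = 3). S. hirsutum matched 1034 transcripts and Moniliophthora roreri 240. Unmatched transcripts took 28.3% ± 0.440 (SD, n = 3). Of the T. versicolor-matched transcripts with at least 20 reads, 434 of 5064 had over 90% of their depth-scaled reads in library A, against 28 in library B and 2 in library C. The corresponding numbers for P. strigosozonata were 5, 8 and 1 of 8875.

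**Figure D1:**
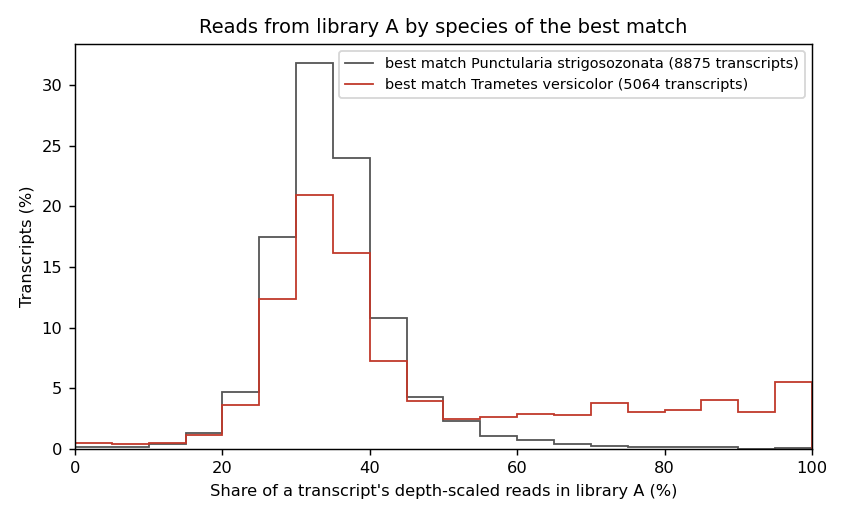
Distribution of the share of each transcript's depth-scaled reads that came from library A (x axis, percent, bins of 5), as the percent of transcripts (y axis), for 8875 transcripts matched to Punctularia strigosozonata and 5064 matched to Trametes versicolor, all with at least 20 reads. The T. versicolor curve has a tail to 100%, with 5.51% of its transcripts in the last bin.

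Agreement between the replicate blocks was then described. Across all 81106 transcripts, Pearson's r of log2(CPM + 1) was 0.983 for libraries A and B, 0.983 for A and C and 0.980 for B and C. Spearman's rho was 0.811, 0.820 and 0.823. The common biological coefficient of variation from edgeR was 0.550, and 0.281 among the 31168 transcripts with at least 10 reads in every library. Of these, 86.5% to 89.9% lay within 2-fold of each other in a pair of libraries. As a check for a library deposited more than once, counts of each pair were compared with sampling noise. The chi-square per transcript had a median of 3.48 to 3.55 and a mean of 55.7 to 88.7, so the libraries were treated as 3 separate ones.

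The next question was which functional groups were abundant in wood-grown mycelium. Of the 33 lists, 32 had members, and 10 of these lay above the central 95% of length-matched random lists. If list members were independent, chance would give 0.8. They are not, as with the 6 autophagy transcripts from 4 assembler genes, so this comparison is no test. Proteasome and ubiquitin products (130 transcripts) lay at the 100th percentile and autophagy products (6 transcripts) at 99.98, and both stayed above the upper limit in all 12 alternatives. Ribosomal proteins (305 transcripts) and oxidative stress products (82) lay at 100, class II peroxidases (91) at 99.99, heat shock proteins and chaperones (148) at 99.93, and housekeeping products (138) at 99.93. The list for glycolysis and the tricarboxylic acid cycle (178 transcripts, 42 of them phosphoglycerate mutase-like proteins) lay at 99.63, and at 79.6 with assembler genes summed. Above the upper limit were also hydrophobins (57), small surface proteins of hyphae, at 99.29, and glutathione S-transferases (60) at 99.06. With at least 10 reads, heat shock proteins and chaperones lay at 91.3, hydrophobins at 95.4 and housekeeping products at 92.2. With the mean of log2 values, heat shock proteins and chaperones lay at 91.7 and hydrophobins at 51.9. With at least 500 bp, heat shock proteins and chaperones lay at 82.9, hydrophobins at 70.6 and glutathione S-transferases at 43.1. With random lists not matched on length, only the proteasome and autophagy lists were still above. Many list members are short fragments, so a list can have a low median and a high percentile for its lengths. Ribosomal proteins had a median of 0.441 RPKM ± 0.339 (SD, n = 3), and all annotated transcripts 0.500 ± 0.0768 (SD, n = 3).

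Some of these lists held transcripts read mainly in library A. With at least 20 reads and over 90% of the depth-scaled reads in library A were 12 of the 57 hydrophobin and 18 of the 305 ribosomal protein transcripts. In these lists 35 and 183 transcripts matched T. versicolor. Of all T. versicolor matches with at least 20 reads, 8.57% had such shares. Whether these transcripts caused the shifts that follow was not tested. Without library A, hydrophobins lay at the 74.4th percentile, ribosomal proteins at 95.6 and housekeeping products at 96.3. Among P. strigosozonata matches alone, heat shock proteins and chaperones lay at 8.64, hydrophobins at 65.7 and glutathione S-transferases at 90.1, while class II peroxidases and ribosomal proteins lay at 100.

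The lists for ABC and major facilitator transporters (477 transcripts, percentile 0.10) and hydrogen peroxide-forming oxidases (96, percentile 1.68) lay below the lower limit. The transporter list lay at 99.75 against a background of all transcripts, 96.0 with assembler genes summed and 46.7 without matching on length. The oxidases lay at 79.4 with assembler genes summed, 71.05 with the mean of log2 values and 60.2 among P. strigosozonata matches. The transporters stayed below the limit in 9 of the 12 alternatives and the oxidases in 4, with 3.14 for the oxidases without library A. Between the limits lay cellobiohydrolases (77.1), endoglucanases (54.2), lytic polysaccharide monooxygenases (24.0), beta-glucosidases (21.1), hemicellulases (14.0), pectinases (18.9), laccases and multicopper oxidases (16.6) and other peroxidases (33.9). Cytochromes P450 (48.2), fungal cell wall enzymes (11.2), peptidases (4.49), oxidative phosphorylation (33.9), oxalate and glyoxylate enzymes (62.3), sugar transporters (16.0) and nitrogen transporters (71.5) also lay between them. Secondary metabolism (4 transcripts) lay at the lower limit itself, and between the limits were recognition (8.42, 12 transcripts) and the lists named for viruses (70.8), plants (56.8) and bacteria (8.70). The transposon list matched 0 transcripts. Of the 20 lists between the limits, 14 lay outside them in at least 1 alternative, and 3 lay above in some and below in others. With 1 library left out, 15 of the 20 moved by more than 1.5 times and 5 fell below the lower limit. These were hemicellulases (2.04 without C), laccases and multicopper oxidases (1.97 without B), fungal cell wall enzymes (1.165 without A and 2.27 without C), peptidases (2.12 without A and 0.73 without C) and secondary metabolism (2.37 without B). Within the limits, cellobiohydrolases went to 35.06 and lytic polysaccharide monooxygenases to 3.88 without A, endoglucanases to 14.365 without C and oxidative phosphorylation to 74.05 without B. Peptidases lay at 99.13 with at least 500 bp and at 99.99 among P. strigosozonata matches, but at 0.23 without matching on length. Oxidative phosphorylation lay at 100 in those first 2 settings, with at least 10 reads and with the mean of log2 values, but at 1.90 without matching on length. Cytochromes P450 lay at 100 against a background of all transcripts, at 0.76 with at least 500 bp and at 1.38 among P. strigosozonata matches.

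Summed reads gave another order. In residual CPM, relative to the counts outside the first 2 transcripts, peptidases had 18543 ± 108 (SD, n = 3), ribosomal proteins 13153 ± 1306 (SD, n = 3) and ABC and major facilitator transporters 12337 ± 1546 (SD, n = 3). Class II peroxidases had 9855 ± 1029 (SD, n = 3). Peptidases differed 1.01-fold between the highest and lowest library, oxidative stress products 1.04-fold and heat shock proteins 1.07-fold. Endoglucanases differed 6.56-fold, with 48.6, 27.4 and 180 residual CPM in libraries A, B and C. Lytic polysaccharide monooxygenases differed 5.28-fold, with 213, 63.6 and 336. The first fold leaned on the high library C and the second on the low library B.

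**Figure D2:**
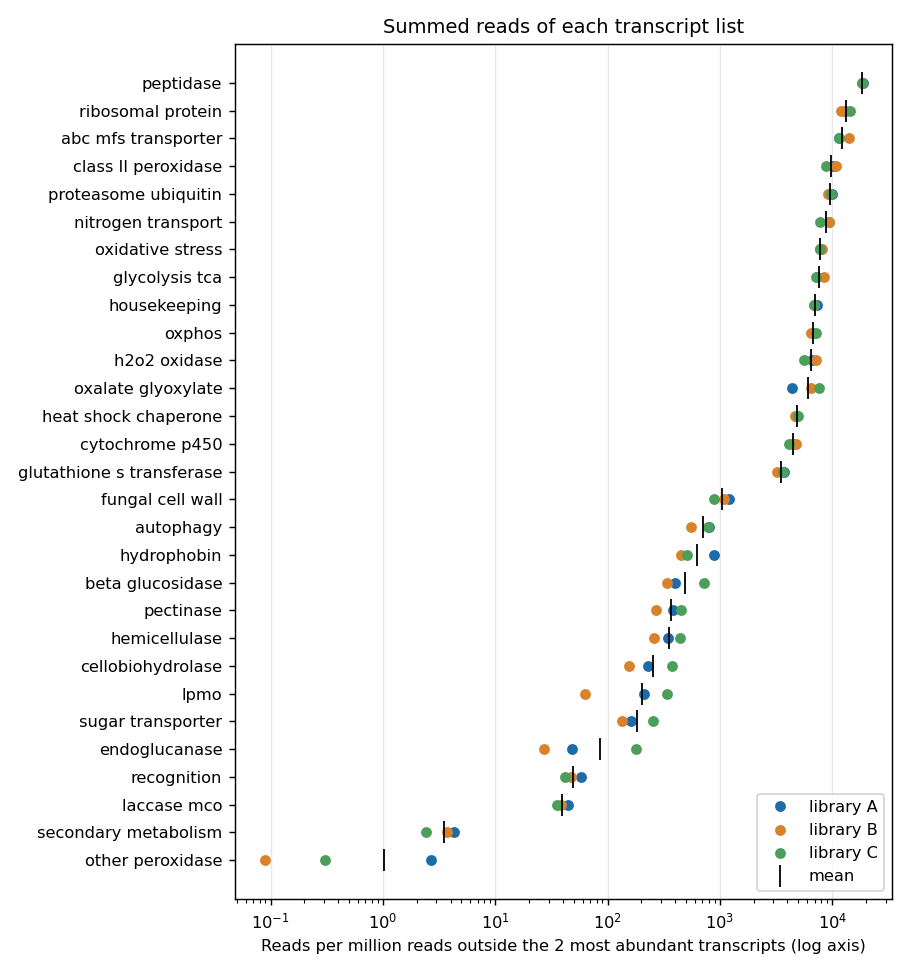
Summed reads of 29 fixed transcript lists (rows) in residual CPM, relative to the counts outside the 2 most abundant transcripts (x axis, log scale), with a point for each library and a black bar at the mean of the 3 libraries. Lists named for other organisms and the empty transposon list are not drawn. Peptidases lie close together near 18543, and endoglucanases spread from 27.4 in library B to 180 in library C.

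Wood cell walls contain cellulose, hemicellulose, pectin and lignin, and the transcript lists related to each were compared. The lignin-related lists included that of hydrogen peroxide-forming oxidases, with its 20 aryl-alcohol dehydrogenases, at 1074 RPKM ± 171 (SD, n = 3). Lignin-related lists (227 transcripts) summed to 4323 RPKM ± 510 (SD, n = 3) and cellulose-related lists (72 transcripts) to 181 ± 113 (SD, n = 3). The cellulose-related mean leaned on library C, with 154, 84.2 and 304 RPKM in libraries A, B and C. Pectin-related transcripts (25) summed to 93.0 RPKM ± 19.6 (SD, n = 3) and hemicellulose-related ones (34) to 59.4 ± 20.6 (SD, n = 3). Most of the pectin-related sum came from 2 isoforms of the same assembler gene, at 37.1 and 31.4 RPKM. Their product name was pectin lyase-like protein, so the pectin-related values rest mainly on that name. The lignin-related sum exceeded the cellulose-related sum in all 3 libraries, by 28.4-fold in library A, 57.2-fold in library B and 12.5-fold in library C. The mean ratio was 32.7 ± 22.7 (SD, n = 3), 20.4 without library B and 19.5 with reads summed without the length. Without products named aryl-alcohol dehydrogenase it was 29.6. Pectin to cellulose was 0.615 ± 0.251 (SD, n = 3), or 0.389 without the length, and hemicellulose to cellulose 0.372 ± 0.109 (SD, n = 3). Among P. strigosozonata matches alone the hemicellulose ratio was 1.37, above 1, and the lignin ratio 115. These ratios depend on product names, since products named by glycoside hydrolase family number were not all in the cellulose-related lists. Family 5 alone had 1275 ± 208 residual CPM (SD, n = 3), against 1030 ± 531 (SD, n = 3) for all cellulose-related lists. Lignin-related lists took 0.501% of all counts in library A (exact 95% interval 0.500 to 0.503), 0.593% in library B (0.591 to 0.595) and 0.441% in library C (0.439 to 0.442). Cellulose-related lists took 0.0266% (0.0263 to 0.0269), 0.0193% (0.0190 to 0.0197) and 0.0497% (0.0492 to 0.0503).

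**Figure D3:**
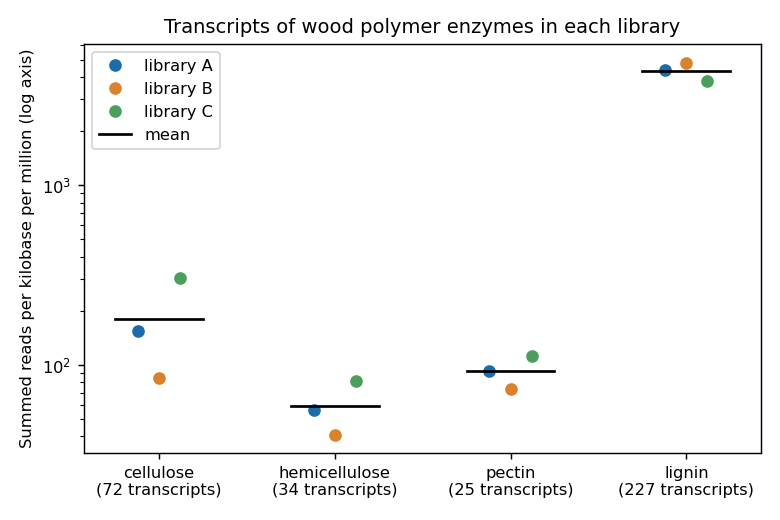
Summed RPKM (y axis, log scale) of the transcript lists related to 4 wood polymers (x axis), with a point for each library and a black line at the mean of the 3 libraries. Lignin-related transcripts lie between 3794 and 4812, above the other areas in every library, and cellulose-related ones lie between 84.2 in library B and 304 in library C.

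Class II peroxidases, the heme enzymes that oxidise lignin, made up most of the lignin-related sum. Their RPKM sum was 284 ± 21.1 (SD, n = 3) times that of laccases and multicopper oxidases and 3.03 ± 0.199 (SD, n = 3) times that of hydrogen peroxide-forming oxidases. The difference from the oxidases was smaller without the length, at 9855 ± 1029 against 6457 ± 817 residual CPM (SD, n = 3). Of the peroxidase transcripts, 69 of 91 were under 500 bp, against 42 of 96 for the oxidases. Laccases and multicopper oxidases had 39.7 ± 4.51 residual CPM (SD, n = 3). The most abundant was TRINITY_DN28428_c0_g3_i2, matched to substrate-free manganese peroxidase PUNSTDRAFT_91363, at 477 RPKM ± 144 (SD, n = 3), followed by TRINITY_DN28428_c0_g3_i4, matched to manganese peroxidase PUNSTDRAFT_74133, at 349 ± 59.7 (SD, n = 3). Both belong to an assembler gene with 11 isoforms, and how reads shared by isoforms were assigned is not given in the sources used here. In the oxidase list, the glyoxal oxidase precursor TRINITY_DN29123_c1_g1_i1 reached 166 RPKM ± 60.3 (SD, n = 3). TRINITY_DN27805_c2_g7_i2, an aryl-alcohol dehydrogenase taken in by the word pattern, reached 185 ± 34.5 (SD, n = 3). The highest laccase, TRINITY_DN28708_c0_g3_i4, reached 1.53 RPKM ± 0.0951 (SD, n = 3), and the next, TRINITY_DN25972_c0_g1_i1, 1.33 ± 0.577 (SD, n = 3).

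Transcripts of the cellulose-related lists were less abundant and varied more between libraries. The cellobiohydrolase II transcript TRINITY_DN23969_c0_g1_i1 had 2273, 164 and 5280 counts in libraries A, B and C, or 22.5 RPKM ± 26.9 (SD, n = 3). The family 61 transcript TRINITY_DN22113_c0_g1_i1, of the lytic polysaccharide monooxygenases, reached 22.9 ± 20.5 (SD, n = 3), and TRINITY_DN13024_c0_g2_i1 11.03 ± 8.60 (SD, n = 3). The endoglucanase TRINITY_DN23921_c0_g1_i1 had 5.54 RPKM ± 5.86 (SD, n = 3) and TRINITY_DN23618_c0_g1_i2 1.74 ± 1.68 (SD, n = 3). The beta-glucosidases TRINITY_DN29643_c0_g1_i2 and TRINITY_DN30308_c1_g3_i2 had 20.2 ± 12.6 and 15.4 ± 7.72 RPKM (SD, n = 3). The acetylxylan esterase TRINITY_DN25086_c1_g1_i2 had 19.8 ± 20.5 (SD, n = 3). TRINITY_DN30299_c0_g1_i1, a xyloglucan-specific cellobiohydrolase counted in both the cellulose and the hemicellulose lists, had 8.62 ± 2.19 (SD, n = 3). It held 52.3% of the pooled reads of the cellobiohydrolase list and 37.1% of those of the hemicellulase list. The hemicellulose to cellulose ratios therefore count it on both sides. The pectin lyase-like isoforms TRINITY_DN25184_c0_g1_i2 and TRINITY_DN25184_c0_g1_i1 had 37.1 ± 6.48 and 31.4 ± 6.06 RPKM (SD, n = 3). Library C carried several of these means. Without it, the mean RPKM was 7.30 for the cellobiohydrolase II transcript, 11.7 and 7.14 for the lytic polysaccharide monooxygenases and 2.29 and 0.771 for the endoglucanases, in the order above. It was 13.2 and 11.02 for the beta-glucosidases and 8.37 for the acetylxylan esterase.

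Among the 20 annotated transcripts with the highest RPKM, 16 matched hypothetical proteins. By species, 17 matched P. strigosozonata, 2 T. versicolor and 1 S. hirsutum. After the first 2 transcripts came the ubiquitin-domain transcript TRINITY_DN6889_c0_g1_i1 at 1553 RPKM ± 330 (SD, n = 3) and TRINITY_DN27788_c0_g1_i1, matched to the hypothetical protein PUNSTDRAFT_140322, at 1473 ± 119 (SD, n = 3). Manganese superoxide dismutase, which removes superoxide, was represented by TRINITY_DN20069_c0_g1_i1 at 744 ± 44.2 (SD, n = 3). The aldo/keto reductase TRINITY_DN23357_c0_g1_i1 reached 706 ± 114 (SD, n = 3) and the glutathione S-transferase TRINITY_DN22268_c0_g1_i1 555 ± 56.5 (SD, n = 3). The short transcript TRINITY_DN1179_c0_g2_i1 of 309 bp had 53223 counts in library A, 3880 in library B and 9544 in library C. Of the 76 transcripts chosen by the naming rule, 9 had a mean RPKM that moved by more than 1.5 times with 1 library left out.

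In energy metabolism and acid turnover, the oxalate decarboxylase TRINITY_DN26863_c0_g1_i1, which cleaves oxalic acid to formate, reached 382 RPKM ± 173 (SD, n = 3) and the formate dehydrogenase TRINITY_DN24004_c0_g1_i1 250 ± 41.0 (SD, n = 3). A subunit of NADH dehydrogenase, TRINITY_DN39485_c0_g1_i1, reached 296 ± 50.3 (SD, n = 3) and transaldolase TRINITY_DN24333_c0_g1_i1 267 ± 20.9 (SD, n = 3). The oligopeptide transporter TRINITY_DN29576_c4_g1_i1 had 238 ± 23.0 (SD, n = 3). The highest transcript of the sugar transporter list, TRINITY_DN28385_c0_g1_i1, had 10.6 ± 6.68 (SD, n = 3), with a mean of 6.78 without library C. That list rests on product names. The major facilitator general substrate transporters TRINITY_DN23542_c0_g1_i1 and TRINITY_DN8445_c0_g1_i1, whose names give no substrate, had 218 ± 71.4 and 213 ± 74.3 (SD, n = 3). The aspartic proteases TRINITY_DN28229_c0_g1_i1 and TRINITY_DN27281_c0_g1_i1 had 287 ± 123 and 277 ± 82.9 RPKM (SD, n = 3). Autophagy-like protein 8, a marker of autophagosomes, had 210 ± 47.0 (SD, n = 3) for TRINITY_DN6627_c0_g1_i1. The transcript TRINITY_DN13430_c0_g1_i1 of 309 bp, matched to the same model PUNSTDRAFT_53150, had 137 ± 70.1 (SD, n = 3). Actin 1 (TRINITY_DN25000_c0_g1_i1) had 205 ± 12.5 (SD, n = 3) and the tubulin beta chain (TRINITY_DN24117_c0_g1_i1) 182 ± 13.3 (SD, n = 3).

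For protection and surface functions, the HSP90 transcript TRINITY_DN28276_c1_g1_i1 had 117 RPKM ± 13.1 (SD, n = 3) and the peroxiredoxin TRINITY_DN24637_c0_g1_i1 280 ± 38.6 (SD, n = 3). The cytochrome P450 TRINITY_DN29530_c1_g4_i1 had 82.8 ± 7.39 (SD, n = 3). Hydrophobin TRINITY_DN31256_c0_g1_i1 had 81.6 ± 13.3 (SD, n = 3) and chitin synthase TRINITY_DN30475_c1_g1_i1, which builds the hyphal wall, 27.5 ± 1.44 (SD, n = 3). A terpene synthase, TRINITY_DN26111_c1_g1_i1, had 0.689 ± 0.197 (SD, n = 3), and the Het-C-domain transcript TRINITY_DN27575_c0_g1_i1, of a family linked to non-self recognition in fungi, 2.85 ± 0.470 (SD, n = 3).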

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

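The choices of restriction to Punctularia strigosozonata matches, omission of aryl-alcohol dehydrogenases and omission of transcripts read mainly in library A were made after the data had been seen, and the others before the data were examined. Libraries could not be tied to replicate numbers, so the replicates were left out as libraries A, B and C. The number of lists above the upper limit of the random lists was 10, was 2 with random lists not matched on length, and was 7 to 10 with a library left out. The number below the lower limit was 2. It was 6 with at least 10 reads, 5 with at least 500 bp, 5 with the mean of log2 values, 1 with assembler genes summed (fungal cell wall enzymes at 1.935, neither of the 2), 1 without the 100 most-read transcripts, 7 with P. strigosozonata matches only, and 3 to 5 with a library left out. The ABC and major facilitator transporter list went from 0.10 to 99.75 against all transcripts, most of which have no match. The cause of these shifts was not tested. The coefficient of variation fell from 0.550 to 0.281 among transcripts with at least 10 reads in every library, and was 0.481 to 0.538 with a library left out, with 0.481 when library A was omitted. Mean Pearson correlation went from 0.982 to 0.977 with that minimum and was 0.980 to 0.983 with a library left out. TMM and DESeq2 scaling moved both by less than the spread between library pairs. The percent of transcripts with a match was 28.6 with at least 10 reads and 35.3 with at least 500 bp, which left 35954 transcripts. The lignin to cellulose ratio stayed above 1 in all 9 alternatives, at 19.5 with reads summed without the length, 115 with P. strigosozonata matches only and 20.4 to 42.8 with a library left out. That restriction also took hemicellulose to cellulose from 0.372 to 1.37, while 0 lytic polysaccharide monooxygenase transcripts remained in the cellulose lists. None of the 9 alternatives added products to the word lists. The other peroxidases, all 5 of them matched to Trametes versicolor, had 2.69, 0.0889 and 0.304 residual CPM in libraries A, B and C.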

Other observations

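Of the tests in this part, those of chance scatter and of switched-on genes in library A were fixed before their results were seen, and the others were chosen after the results had been seen. The groupings and transcripts in the next paragraph were also chosen after their values were seen.

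By glycoside hydrolase number in the product name, family 16, which includes enzymes acting on beta-1,3-glucans, had the most reads, at 3971 ± 251 residual CPM (SD, n = 3) over 31 transcripts. Family 5 had 1275 ± 208 (SD, n = 3), family 13 752 ± 98.1 (SD, n = 3) and family 92 751 ± 119 (SD, n = 3). Among 3316 named products with at least 1000 reads and 500 bp, the median range between libraries was 0.44 on the log2 scale. The cellobiohydrolase II transcript TRINITY_DN23969_c0_g1_i1 had the widest, at 5.10, and 19 of the 25 widest were lowest in library B, as were 30.9% of all 3316. The glucoamylase TRINITY_DN28001_c0_g2_i1, which releases glucose from starch, had 1408, 27 and 110 counts in libraries A, B and C. Isocitrate lyase TRINITY_DN25893_c0_g1_i1, of the glyoxylate cycle, had 648, 1747 and 2887 counts, and glutamate decarboxylase TRINITY_DN26707_c1_g1_i1 had 4949, 1835 and 337. The third most abundant transcript of all, TRINITY_DN6660_c0_g1_i1 of 2225 bp, had no match and took 6379 RPKM ± 2087 (SD, n = 3).

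Transcripts matched to Trametes versicolor often had nearly all their reads in library A, as 8.57% of those with at least 20 reads did, against 0.125% of Punctularia strigosozonata matches weighted to the same read counts. Chance scatter was argued against, since 100 negative binomial draws with the common spread gave a mean of 0.93 such transcripts, with 4 at most, against 434. These draws gave every transcript the same spread. The estimate was 0.550 over all transcripts and 0.281 with at least 10 reads in every library. Scatter at low reads may therefore be understated. If genes of V. comedens were switched on in 1 block, ribosomal protein, oxidative phosphorylation and housekeeping products would be rarer among these transcripts. Such products made up 5.99% of these transcripts (exact 95% interval 3.95 to 8.65) and 3.35% of the other T. versicolor matches. This went against the prediction, but the 2 sets were not matched on length or reads. Of the 26 such products in library A, 18 were ribosomal proteins, a list with 189 of 305 transcripts under 500 bp. The test therefore does not decide whether genes were switched on. The 434 transcripts did not hold the whole excess. Shares in library A from 70% to 75% were found for 3.75% of T. versicolor matches with at least 20 reads. This compared with 0.203% of P. strigosozonata matches. For shares from 80% to 85%, the values were 3.18% and 0.146%. The 434 transcripts held 646 residual CPM of library A, and reads on transcripts with these lower shares were not summed. Reads of another fungus in library A remain a candidate explanation, although the 8.57% restates how the pattern was noticed. Whether such reads came from the wood, the handling or the sequencing run was not tested, and no sequences were compared.

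The cellulose-related lists had 887, 586 and 1618 residual CPM in libraries A, B and C, and 30 of the 41 members with at least 20 reads (73.2%) were lowest in library B, against 40.0% of all annotated transcripts with as many reads. The ratio of library C to library B was 2.76, and library scaling was argued against as its whole cause, since relative to the housekeeping list of the same library, where a scaling factor cancels, it was 2.74 (95% counting interval 2.68 to 2.80). The spread of random lists was argued against too, because 0 of 10000 lists matched on reads reached 2.76 and their highest ratio was 1.75, although genes of one pathway may vary together more than random ones. Another organism in libraries A and C cannot be told apart from a difference between blocks, since 0 of 43 transcripts low in library B were ribosomal, oxidative phosphorylation or housekeeping products, which allows up to 8.22%, against 3.17% of the others. The ratio was 1.62 among P. strigosozonata matches, and no biological explanation was tested, as the design holds 1 group.

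The 2 transcripts that held most reads may be ribosomal RNA carried through the selection of mRNA. The model matched by the first was the best match of 47 assembled transcripts and that of the second of 11, where the median model had 2. As 98.9% of models had fewer than 11, the second stayed under the bound of 99% set for this test. A very abundant mRNA could also be assembled into many transcripts, so the test cannot decide on either side of that bound. Ribosomal RNA cannot be told apart from abundant mRNA without the sequences. No biological explanation was tested.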
